A study of Mus musculus with 18 samples.

How the data were processed

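RNA from the ileum of C57BL/6 mice, the inbred laboratory strain, was measured on Affymetrix GeneChips, short-oligonucleotide arrays on which several probes per transcript form a probe set. Per the labels, the pieces held all layers of the small intestine, so that epithelium, muscle, nerve, vessels and immune cells all contributed RNA. Per the labels' protocols, cDNA was primed from poly-A tails with a T7 oligo-dT primer. The labels give 6 postnatal ages with 3 individual mice each, 18 arrays in all, and name no batch, sex or litter.

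The deposited values are log2 expression levels per probe set, made with RMA per the submitters' processing notes, which give neither a version nor options. RMA corrects each array's background, brings the arrays to a common distribution and summarises the probes of a set. The table holds 45101 probe sets, 64 of them controls, with no missing value. Values ran from 1.68 to 13.71 and the array medians from 3.88 to 3.97. The table gives no detection calls, so a level near those medians could not be separated from background, and a fold against such a level depends on the background correction. Array model and scan dates are not given in the sources used here.

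Gene names came from the platform annotation, which listed 35890 probe sets, 34945 of them with 1 symbol and 932 with several; 9211 were not listed and are unnamed here. Entrez identifiers matched 34754 probe sets to the gene table of the mouse assembly GRCm38.p6, and 0 symbols changed. Probe sets with several symbols were left out. A gene was represented by the probe set with the highest mean over the 18 arrays, among those that reached log2 6 on at least 3 arrays; 18193 genes had a probe set with 1 symbol and 8630 genes were tested. Probe sets of near-identical genes, such as alpha-defensins, immunoglobulin segments and the lysozymes, can read each other's transcripts, and their values are uncertain to that extent.

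Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with age as a factor with 6 levels and all 18 arrays sharing 1 estimate of the spread, which left 12 residual degrees of freedom. The median residual SD was 0.176 on the log2 scale. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called below 0.05. The comparisons were an F test over all ages, the mean of days 24 and 32 minus the mean of days 4, 7, 9 and 11, day 11 minus day 4, day 24 minus day 11, day 32 minus day 24, and each step between adjacent ages from day 4 to day 11. The labels place the series from before to after weaning without giving the day; weaning was put between day 11 and day 24 from general knowledge of laboratory mice. Errors of differences are standard errors from the fit, and errors of levels are standard deviations over the arrays.

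Before the data were examined, 30 gene lists were fixed from general knowledge of the postnatal ileum and of other tissues a full-thickness piece could hold. Each was tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison, beside the number of members called over all genes and adjusted over the list alone. A correlation estimated for each list was the alternative. List members were matched by exact symbol; 29 lists had a measured member, and members without one were not analysed here. The rule for named genes was fixed at the same time. It took the 5 largest rises and 5 largest falls (3 and 3 for day 24 minus day 11) among called genes whose arrays did not overlap between the sides. To these it added up to 4 called members of each list with the largest change, up to 2 in the later comparisons, and a set of sentinel genes (Lct, Arg2, Treh, Prdm1, Fabp6, Slc10a2, Fgf15, Lyz1, Pigr, Reg3b, Reg3g and Igf2). In steps between adjacent ages it took up to 2 genes each way with the smallest adjusted p. The sentinels Sis, Ass1, Camp and H19 were not analysed here. Xist and Eif2s3y were named after their values were seen.

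The alternatives fixed beforehand were no filter on dim probe sets, a filter at log2 8, the mean of a gene's probe sets, quantile, median and cyclic loess normalization on top of the deposited values, trend and robust options in eBayes, array weights, only the arrays of the ages compared, and each array left out in turn. Added after seeing the data were the hybridization group of the arrays as a block, the 10 arrays of the higher such group alone, the log2 level of Xist as a covariate, and 3 arrays left out for their control probe sets. Also added were 3 marker lists and 20 gene families chosen by symbol.

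The fit was tested on simulated data with the real means and spread for 8630 genes, 200 of them changed, in a single draw per comparison. Genes were drawn independently of each other, whereas in the data 6292 genes were called between the stages and list members were correlated. The shares therefore need not hold for the real data. For day 32 minus day 24 it recovered 37.3% of the changes of log2 0.5, 95.5% of log2 1 and 97.0% of log2 2. For the difference between stages the shares were 88.1%, 100% and 100%, and for day 11 minus day 4 they were 41.8%, 97.0% and 100%. False calls made up 4.38% of the calls for day 32 minus day 24 and 4.22% for day 11 minus day 4, and 6.34% (13 calls) for the difference between stages, above the level of 5% aimed at. For arrays, their number limits the precision, here 3 per age. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.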

Results

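The series followed gene expression in the mouse ileum, the last part of the small intestine, from suckling to after weaning. Pieces of full thickness were taken on postnatal days 4, 7, 9, 11, 24 and 32, from 3 individual mice each, giving 18 arrays. The first 4 ages (12 arrays) were grouped as before weaning and the last 2 (6 arrays) as after weaning, a division taken from general knowledge of mice. Within an age, arrays correlated at 0.983 or more across probe sets, and no arrays held identical values. The level of Xist, the transcript of the inactive X chromosome of females, was 8.68 to 10.13 on 10 arrays and 3.86 to 5.12 on the other 8. Eif2s3y, a Y-linked gene, ran the opposite way, at 6.97 to 7.68 on the 8 arrays with low Xist and 1.99 to 2.63 on the 10 others. The male pattern was present on 3 of 12 arrays before and 5 of 6 after weaning. Day 7 replicate 3 and day 9 replicate 2 share a number in their titles but had opposite patterns, with Xist at 4.69 and 9.74, and correlated at 0.993 across probe sets.

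Of 8630 genes tested, 5897 changed across the 6 ages (limma F test). The first principal component carried 81.9% of the variance and separated the ages up to day 11 from days 24 and 32, and the next carried 4.79%. Lct, the lactase that digests milk sugar, held a log2 level of 11.42 ± 0.20 on day 4 and 11.23 ± 0.15 on day 11, then 9.60 ± 1.14 on day 24 and 3.41 ± 0.38 on day 32 (SD, n = 3 each). Treh, the trehalase of the adult brush border, went from 3.04 ± 0.26 on day 11 to 8.47 ± 0.29 on day 24. Lyz1, the lysozyme of Paneth cells, already stood at 9.00 ± 0.19 on day 4 and reached 10.26 ± 0.10 on day 11 and 13.09 ± 0.13 on day 24. Fabp6, the bile acid binding protein of ileal enterocytes, passed from 8.30 ± 0.07 on day 4 through 5.77 ± 0.50 on day 11 to 13.09 ± 0.19 on day 24.

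**Figure D1:**
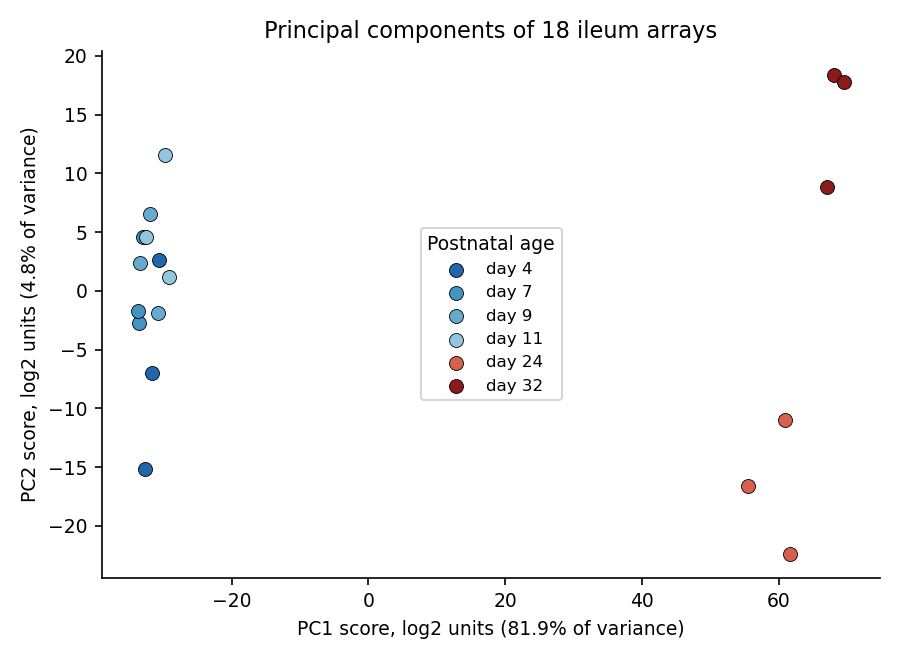
Scores of the 18 arrays on the principal components of the log2 values of 8630 genes; each point is 1 array, coloured by postnatal age. PC1 (81.9% of the variance) parts the 12 arrays of days 4 to 11 from the 6 arrays of days 24 and 32, and PC2 carries 4.79%.

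**Figure D2:**
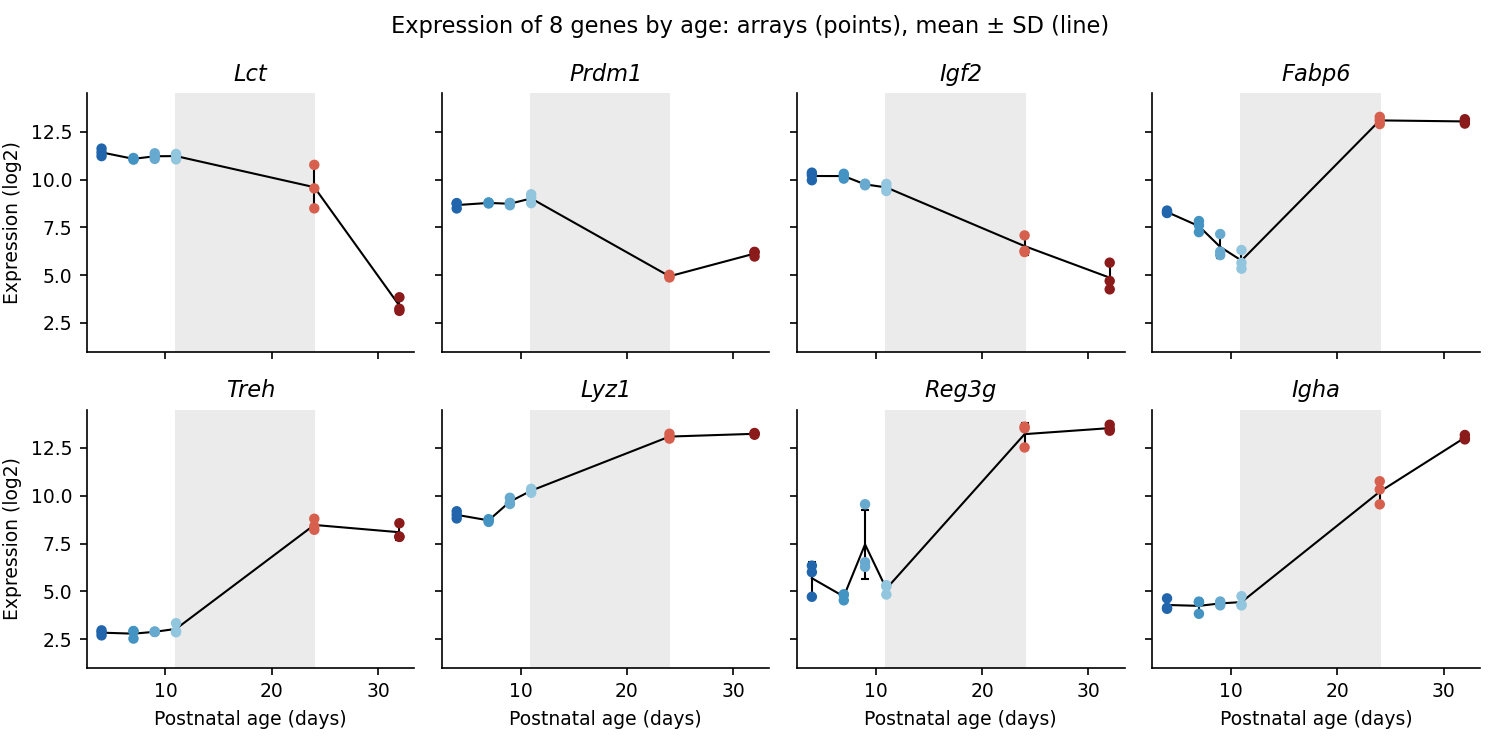
Log2 expression of 8 genes against postnatal age in days; points are single arrays (3 per age), the line joins the means and bars are SD. The grey band spans day 11 to day 24, in which no age was sampled; Lct ends at 3.41 on day 32, while Fabp6 reaches 13.09 and Lyz1 13.09 on day 24.

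The comparison of days 24 and 32 with days 4 to 11 asked which genes differ between the ileum after and before weaning. After weaning the goblet cell lectin Zg16 was 412-fold higher (log2 difference 8.69 ± 0.08, SE, n = 6 against 12; adjusted p = 1.13e-22), rising from a level of 4.38 to 13.06. Next came the sulfate transporter Slc13a1 (204-fold, log2 7.67 ± 0.09), the antimicrobial lectin Reg3g (198-fold, 7.63 ± 0.36), the IgA heavy chain Igha (157-fold, 7.29 ± 0.15) and the cytochrome P450 Cyp4f14 (137-fold, 7.10 ± 0.10). The largest falls were in Folr1, a folate receptor (400-fold lower, log2 difference -8.65 ± 0.10, adjusted p = 2.40e-21), and Meltf, an iron-binding membrane protein of the transferrin family (329-fold, -8.36 ± 0.13). Mcoln3, an endolysosomal cation channel, was 183-fold lower (-7.52 ± 0.09), Mamdc4, a glycoprotein of apical endosomes in the suckling gut, 158-fold lower (-7.31 ± 0.13), and Afp, alpha-fetoprotein, 127-fold lower (-6.99 ± 0.18). The dim side of several of these lay near or below the array medians of 3.88 to 3.97, as with Folr1 at 3.42, Mcoln3 at 2.62 and Afp at 3.91 after weaning and Slc13a1 at 2.70 before it. Their folds and the order of those folds depend on the background correction.

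Of 14 measured suckling enterocyte genes 13 fell and 0 rose (median log2 difference -2.76; camera adjusted p = 5.18e-07, adjusted p = 0.0705 with an estimated correlation). Among them Mamdc4 was 158-fold, Lct 26.6-fold, the endocytic adaptor Dab2 19.5-fold and the lysosomal protease Ctsl 15.5-fold lower, and Prdm1, a transcriptional repressor, had a log2 difference of -3.26. Of 15 genes of adult brush border digestion and sugar uptake 12 rose and 3 fell (camera adjusted p = 6.84e-05, adjusted p = 0.0705 with an estimated correlation). The mitochondrial arginase Arg2 rose 48.1-fold, Treh 42.1-fold, the peptide transporter Slc15a1 7.55-fold and the aminopeptidase Anpep 6.86-fold. In ileal bile acid handling 5 of 8 genes rose and 3 fell (camera adjusted p = 0.0360, adjusted p = 0.155 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.0675). Fabp6 rose 65.8-fold, the bile acid importer Slc10a2 40.5-fold and the exporter subunit Slc51b 8.04-fold, whereas the canalicular-type exporter Abcc2 was 18.1-fold lower and the ileal hormone Fgf15 had a log2 difference of -1.46.

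All 5 measured Paneth cell genes rose (median 4.00; camera adjusted p = 1.11e-05, adjusted p = 0.0705 with an estimated correlation), with the lectin Itln1 38.7-fold, the antimicrobial ribonuclease Ang4 20.5-fold, the phospholipase Pla2g2a 16.0-fold and Lyz1 13.4-fold higher. All 11 goblet cell genes rose (camera adjusted p = 2.60e-06, adjusted p = 0.0705 with an estimated correlation), among them Zg16, Retnlb (9.40-fold), the secretory lineage factor Atoh1 (4.57-fold) and Clca1 (4.17-fold). All 6 genes of microbe-responsive epithelial defence rose (camera adjusted p = 7.69e-05, adjusted p = 0.105 with an estimated correlation): Reg3g, the serum amyloid Saa1 (115-fold; log2 6.85, or 7.92 without day 24 replicate 1), Reg3a (108-fold) and Reg3b (9.79-fold). Pigr, which carries IgA across the epithelium, rose 8.88-fold. Of 7 innate sensing genes 5 rose and 2 fell (camera adjusted p = 0.0822); the double-stranded RNA receptor Tlr3 rose 7.53-fold, the kinase Irak1 1.65-fold and the adaptor Myd88 1.42-fold.

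After weaning all 5 measured B cell and plasma cell genes rose (camera adjusted p = 0.00148, adjusted p = 0.163 with an estimated correlation), led by Igha, the joining chain Jchain (133-fold) and Mzb1 (4.07-fold). Cd79b, also among them, had a log2 difference of 1.47, or 0.80 without day 32 replicate 1. All 4 genes of T cells and intraepithelial lymphocytes rose (camera adjusted p = 0.0133, adjusted p = 0.163 with an estimated correlation), with the granzymes Gzmb 5.59-fold and Gzma 4.12-fold and the chemokine Ccl5 3.34-fold higher. The remaining call, Zap70, ended without any of several single arrays, such as day 4 replicate 3 (log2 0.17, limma adjusted p = 0.0512) or day 24 replicate 2 (0.15, 0.0813). All 9 MHC class I presentation genes rose (camera adjusted p = 0.000432, adjusted p = 0.160 with an estimated correlation), such as the peptide transporter Tap1 (2.84-fold) and the immunoproteasome subunit Psmb10 (2.54-fold). All 5 MHC class II genes rose (camera adjusted p = 0.0173, adjusted p = 0.354 with an estimated correlation), such as H2-DMa (2.37-fold). Here too the stage mean joins unlike ages. From day 11 to day 24, 1 of the 5 rose (median 0.25, camera adjusted p = 0.289), and from day 24 to day 32 all 5 (median 0.91). Over these intervals the T cell list had medians of 0.86 (camera adjusted p = 0.112) and 2.30 (0.000136). Of 11 interferon-stimulated genes 7 rose and 3 fell (camera adjusted p = 0.122); Gbp2 rose 3.48-fold and Ifit1 was 2.42-fold lower. Of 8 macrophage and dendritic cell genes 1 rose and 2 fell (camera adjusted p = 0.979), and the list median of -0.01 turned to 0.06 under quantile and cyclic loess normalization and to 0.00 under median centring. Lyz2, close in sequence to Lyz1, rose 12.3-fold, while the receptor Csf1r was 7.45-fold and Cd68 2.37-fold lower.

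All 11 measured genes of the imprinted growth network fell (median -2.61; camera adjusted p = 5.52e-06, adjusted p = 0.0705 with an estimated correlation). The growth factor Igf2 was 18.8-fold, the cell cycle inhibitor Cdkn1c 17.3-fold, the non-coding RNA Meg3 11.3-fold and Mest 10.4-fold lower. All 13 genes of extracellular matrix and fibroblasts fell (camera adjusted p = 0.000439, adjusted p = 0.237 with an estimated correlation), with elastin (Eln) 3.30-fold, periostin (Postn) 2.50-fold and the collagen Col5a1 2.39-fold lower. Of 5 enteric neuron and glia genes 4 fell (camera adjusted p = 0.0885): Uchl1 (2.62-fold), the receptor Ret (2.50-fold), Prph (2.48-fold) and Nos1 (1.35-fold). Of 8 smooth muscle genes 2 rose and 1 fell (camera adjusted p = 0.453); the actin-binding Cnn1 rose 1.41-fold and Acta2 was 1.28-fold lower. Of 19 cell cycle genes 10 rose and 2 fell (camera adjusted p = 0.0133, adjusted p = 0.390 with an estimated correlation), including the mitotic genes Aurkb (2.10-fold), Ccnb2 (2.10-fold), Plk1 (1.97-fold) and Cdc20 (1.87-fold). Among 6 crypt stem cell and Wnt target genes 3 rose and 1 fell (camera adjusted p = 0.445). Axin2 rose 2.01-fold and Olfm4 1.56-fold. The remaining rise, Cdca7 (log2 0.24), lost its call without any of several single arrays. Among these were day 24 replicate 2 (0.14, limma adjusted p = 0.159) and day 4 replicate 2 (0.22, 0.0557).

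Of 14 genes of lipoprotein assembly and fat absorption 11 fell and 3 rose (camera adjusted p = 0.0282, adjusted p = 0.237 with an estimated correlation). The fatty acid binding protein Fabp1 was 29.7-fold, the apolipoproteins Apoa4 11.1-fold and Apoc3 7.15-fold, and the lipid droplet protein Plin2 6.96-fold lower. Of 11 fatty acid oxidation and ketogenesis genes 7 fell and 3 rose (camera adjusted p = 0.194); the thiolase Acaa2 was 5.10-fold lower and the lipase inhibitor Angptl4 rose 2.32-fold. Of 14 cholesterol synthesis genes 13 rose and 1 fell (camera adjusted p = 6.81e-05, adjusted p = 0.204 with an estimated correlation), with Sqle 3.64-fold, Cyp51 2.76-fold and Idi1 2.74-fold higher. All 12 xenobiotic metabolism genes rose (camera adjusted p = 1.11e-05, adjusted p = 0.155 with an estimated correlation), such as the carboxylesterase Ces1f (25.1-fold) and the cytochromes Cyp2d26 (18.7-fold), Cyp3a11 (11.1-fold) and Cyp4b1 (9.76-fold). Glucocorticoid-induced genes went both ways, 5 higher and 4 lower of 10 (camera adjusted p = 0.453); Fkbp5 rose 4.11-fold and the metallothionein Mt2 was 4.22-fold lower. Of 10 enteroendocrine genes 2 rose and 4 fell (camera adjusted p = 0.530), the hormones Gip (2.76-fold), Cck (2.10-fold), Pyy (1.73-fold) and Nts (1.71-fold) being lower. The stage mean of this list joins unlike ages. From day 11 to day 24, 3 of the 10 rose and 1 fell (median 0.30, camera adjusted p = 0.247), and from day 24 to day 32 Gip had a log2 difference of -3.54.

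Markers of tissues outside the gut wall were measured as well. Of 5 adipocyte genes 4 rose and 1 fell (camera adjusted p = 0.0258, adjusted p = 0.237 with an estimated correlation), with adiponectin (Adipoq) 43.5-fold, the carbonic anhydrase Car3 39.7-fold and Retn 8.76-fold higher. Both measured hepatocyte genes fell (camera adjusted p = 0.0133, adjusted p = 0.106 with an estimated correlation), Ttr 68.3-fold and Fga 9.24-fold. Of 2 measured pancreatic acinar genes the colipase Clps rose 3.14-fold and Cela1 had a log2 difference of -0.15 with an adjusted p of 0.46 (camera adjusted p = 0.245). The 1 measured erythroid gene, Alas2, was 2.48-fold lower (camera adjusted p = 0.291), and 0 mast cell genes were measured.

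Among the other genes named for this comparison, the dim side also lay below the highest array median of 3.97 for Arg2, Treh, Slc10a2, Pla2g2a, Retnlb, Saa1, Reg3a, Tlr3, Jchain, Gzmb, Ccl5, Ces1f, Cyp3a11, Adipoq and Fga. Their folds depend on the background correction likewise. In all, 2681 genes were higher and 3611 lower after weaning, 655 and 997 of them at least 2-fold. The balance depended on the setting: the numbers were 3061 and 3301 with quantile and 3132 and 3253 with cyclic loess normalization, and without a filter on dim probe sets more were higher (5248) than lower (4999). For each list the counts adjusted over the list alone were the same as those over all genes, and 18 of 29 lists passed camera at the preset correlation but 0 with an estimated one. The probe sets for poly-A controls, spike-in RNAs that can be added before labelling, had a level of 4.17 ± 0.26 on the 12 arrays before and 5.73 ± 0.50 on the 6 arrays after weaning, with ranges of 3.63 to 4.61 and 5.15 to 6.64. The 18S ribosomal RNA control probe sets read 6.15 ± 0.89 before and 9.04 ± 1.62 after weaning (SD, n = 12 and 6), with ranges of 4.93 to 8.19 and 7.01 to 10.85. Hybridization spike controls put the 6 arrays after weaning and 4 of the arrays before it in a higher group and the other 8 in a lower one; with this group as a block 2661 genes were higher and 3064 lower, and within the higher group 2363 and 2765, while the lower group held no array after weaning.

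**Figure D3:**
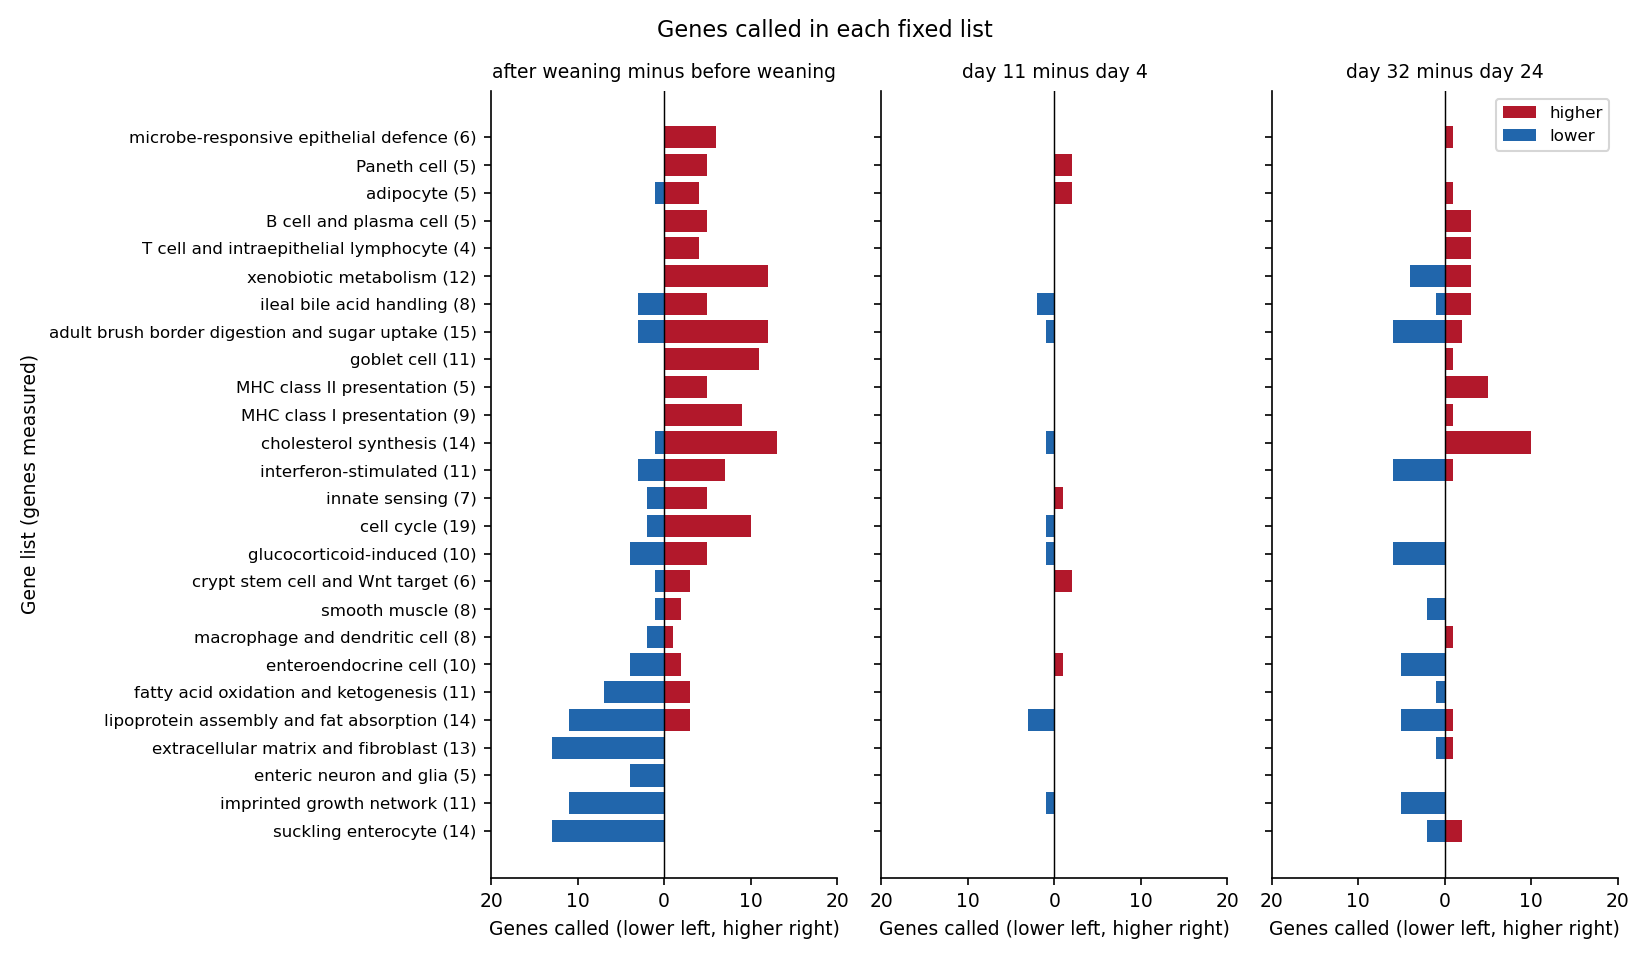
Number of genes called higher (right) and lower (left) in each gene list with at least 3 measured genes, for 3 comparisons; the number measured is in parentheses. After weaning 13 of 14 suckling enterocyte genes were lower and all 12 xenobiotic metabolism genes higher, whereas from day 4 to day 11 no list had more than 3 calls.

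The difference of day 11 and day 4 covered the sampled suckling period. Among the largest rises, Car3 was 33.3-fold higher on day 11 (log2 5.06 ± 0.44, SE, n = 3 against 3; adjusted p = 4.30e-06), the alpha-defensin Defa39 8.37-fold (3.06 ± 0.19), Itln1 6.55-fold (2.71 ± 0.15), Adipoq 4.39-fold (2.14 ± 0.42) and the fatty acid desaturase Scd1 4.11-fold (2.04 ± 0.33). Fabp6 was 5.81-fold lower (log2 difference -2.54 ± 0.25, adjusted p = 1.35e-05), Fabp1 4.45-fold (-2.15 ± 0.33), the lipase-family gene Abhd3 3.83-fold (-1.94 ± 0.24), Sectm1b 3.02-fold (-1.59 ± 0.17) and the ectoenzyme Bst1 2.81-fold (-1.49 ± 0.24). The levels of Car3 (3.51), Adipoq (2.56) and Scd1 (3.71) on day 4 lay below the array medians, so their folds depend on the background correction. In all 116 genes were higher and 133 lower, 20 and 13 of them at least 2-fold.

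Of the 5 Paneth cell genes 2 rose, Itln1 and Lyz1 (2.40-fold) (camera adjusted p = 2.13e-06, adjusted p = 0.0546 with an estimated correlation). Of 6 crypt stem cell and Wnt target genes 2 rose, and 3 adjusted over the list alone (camera adjusted p = 5.96e-05, adjusted p = 0.0546 with an estimated correlation). The stem cell receptor Lgr5 was 2.29-fold higher and Tnfrsf19 had a log2 difference of 0.63. Of 14 genes of lipoprotein assembly and fat absorption 3 fell, and 6 adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.210 with an estimated correlation), with Fabp1, Apoc2 (log2 difference -0.77) and Fabp2 (1.64-fold) lower. In the cholesterol synthesis list 1 of 14 genes fell, and 6 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 3.24e-05, adjusted p = 0.288 with an estimated correlation). Among 19 cell cycle genes Ccnb2 fell (1.52-fold) and the median was -0.32 (camera adjusted p = 7.24e-05, adjusted p = 0.315 with an estimated correlation). Of 13 matrix and fibroblast genes 0 passed over all genes and 5, all higher, adjusted over the list alone, with a median of 0.39 (camera adjusted p = 1.03e-05, adjusted p = 0.244 with an estimated correlation). Of the 5 adipocyte genes 2 rose, Car3 and Adipoq, and 3 adjusted over the list alone (camera adjusted p = 0.000606, adjusted p = 0.210 with an estimated correlation). Both hepatocyte genes fell, Ttr 1.69-fold and Fga 1.64-fold (camera adjusted p = 0.00394, adjusted p = 0.0972 with an estimated correlation), and of the 2 pancreatic acinar genes 1 fell, Cela1 2.80-fold (camera adjusted p = 0.00882, adjusted p = 0.215 with an estimated correlation). Of 14 suckling enterocyte genes 0 passed, with Lct at a log2 difference of -0.19 and an adjusted p of 0.820.

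The counts from day 4 to day 11 rested on single arrays: without day 4 replicate 2, 50 genes were higher and 42 lower, without day 4 replicate 3, 51 and 34, without day 11 replicate 1, 61 and 38, and without day 11 replicate 2, 64 and 69. With the hybridization group as a block they were 187 and 297, with array weights 381 and 563, and with only the arrays of days 4 and 11 they were 28 and 24. The split moved both ways with normalization, to 171 higher and 120 lower with cyclic loess and to 98 and 165 with median centring. The Adipoq call ended without day 4 replicate 3 (log2 2.07, adjusted p = 0.0536) and its value was 1.48 without day 11 replicate 3. The Ttr call ended without day 4 replicate 2 (-0.74), day 4 replicate 3 (-0.80) or day 11 replicate 1 (-0.67). The Cela1 call ended without day 4 replicate 2 (-1.26) or day 11 replicate 1 (-1.35). The Fga call ended without day 4 replicate 1 (-0.56), day 4 replicate 3 (-0.67), day 11 replicate 1 (-0.72) or day 11 replicate 3 (-0.64). That of Apoc2 ended without day 4 replicate 2 (-0.64), day 4 replicate 3 (-0.75), day 11 replicate 1 (-0.69) or day 11 replicate 2 (-0.77). Tnfrsf19 lost its call without day 4 replicate 1 (0.54), day 4 replicate 2 (0.64), day 11 replicate 1 (0.63) or day 11 replicate 3 (0.52). With only the arrays of days 4 and 11 the calls of Lgr5 (limma adjusted p = 0.0718), Ccnb2 (0.0848), Adipoq (0.0944), Apoc2 (0.0974), Tnfrsf19 (0.129) and Fga (0.151) ended. Without the 3 arrays with the widest Gapdh gaps, an omission chosen after seeing the data, Lgr5 had a log2 difference of 0.79 (adjusted p = 0.123) in place of 1.19, and the calls of Bst1 (-1.11), Cela1 (-1.13) and Ttr (-0.66) ended as well.

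Between adjacent suckling ages 7, 4 and 4 genes were called for the steps to days 7, 9 and 11, but 114, 207 and 354 with array weights. From day 7 to day 9 there were 4, all higher on day 9: Itln1 (4.57-fold, log2 2.19 ± 0.15, n = 3 against 3; adjusted p = 3.52e-07), Defa39 (4.81-fold), Lyz1 (1.97-fold) and Pigr (2.23-fold). From day 9 to day 11 there were 4: Car3 (9.17-fold) and Itln1 (2.00-fold) rose, Pm20d1 was 1.75-fold lower, and the chromatin gene Setd5, named after its value was seen, rose 1.74-fold. From day 4 to day 7 there were 7, among which Anxa8 (2.15-fold) and Rsrp1 (2.00-fold) rose and Sectm1b (2.32-fold) and the respiratory complex assembly factor Ndufaf4 (1.64-fold) fell. At an unadjusted p under 0.05 the numbers were 512, 208 and 608 for the steps to days 7, 9 and 11. The count for day 4 to day 7 was 0 without day 4 replicate 2, day 7 replicate 2 or day 7 replicate 3, 4 without day 9 replicate 1, and 3 without day 7 replicate 1, day 9 replicate 2, day 9 replicate 3, day 11 replicate 2 or any 1 array of day 32. The count for day 9 to day 11 was 0 without day 9 replicate 1, day 9 replicate 3 or day 11 replicate 3, 1 without day 11 replicate 1, and 2 without day 4 replicate 3, day 7 replicate 3 or day 32 replicate 2. The counts for both of these steps were 0 with only the arrays of the ages compared and also without the 3 arrays with the widest Gapdh gaps. With the hybridization group as a block the calls of Ndufaf4 (adjusted p = 0.0877), Pm20d1 (0.101) and Setd5 (0.101) ended. Car3 had a log2 difference of 3.20 in the step to day 11, or 3.92 without day 9 replicate 2.

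Day 24 minus day 11 spanned weaning. Zg16 rose 395-fold (log2 8.63 ± 0.13, SE, n = 3 against 3; adjusted p = 7.07e-19), Reg3g 271-fold (8.08 ± 0.59) and Fabp6 161-fold (7.33 ± 0.25). Folr1 was 368-fold lower (log2 difference -8.52 ± 0.16), Meltf 335-fold (-8.39 ± 0.22) and Mcoln3 189-fold (-7.56 ± 0.15). On day 24 Folr1 (3.58) and Mcoln3 (2.64) lay below the array medians and Meltf (4.16) near them. On day 11 Arg2 (2.50), Treh (3.04) and Slc10a2 (2.04) lay below them. These folds and their order depend on the background correction. Of 14 suckling enterocyte genes 13 fell (camera adjusted p = 8.47e-09, adjusted p = 0.0402 with an estimated correlation), with Mamdc4 145-fold, Dab2 17.6-fold and Prdm1 16.8-fold lower. Lct, by contrast, had a log2 difference of -1.63, or -1.07 without day 24 replicate 3. The lists of the adult brush border (11 of 15 higher, 2 lower; Arg2 59.3-fold, Treh 43.3-fold), Paneth cells (5 of 5 higher; Ang4 19.7-fold) and imprinted genes (11 of 11 lower; Meg3 11.3-fold, Igf2 8.38-fold) likewise passed camera with an estimated correlation, each with an adjusted p of 0.0402. Fgf15 was 5.14-fold lower (log2 difference -2.36, or -1.70 without day 24 replicate 1), and Slc10a2 rose 26.8-fold. Beside these lists, the 18S control probe sets went from 6.52 ± 1.45 to 10.47 ± 0.33 and the poly-A controls from 3.93 ± 0.33 to 5.61 ± 0.12 (SD, n = 3 each). Another 9 lists passed camera only at the preset correlation. With an estimated correlation the adjusted p was 0.0827 for goblet cells (11 of 11 higher) and hepatocytes (2 of 2 lower), 0.0886 for epithelial defence (6 of 6 higher) and 0.151 for xenobiotic metabolism (10 of 12 higher). It was 0.225 for matrix and fibroblasts (13 of 13 lower), MHC class I presentation (7 of 9 higher) and B and plasma cells (4 of 5 higher), 0.290 for cholesterol synthesis (12 of 14 higher, 1 lower) and 0.380 for the cell cycle (9 of 19 higher, 1 lower). In all 2318 genes were higher and 2791 lower, and with the hybridization group as a block 2454 and 2551. The larger side changed with quantile normalization, to 2663 higher and 2556 lower, and without a filter on dim probe sets, to 3633 and 3528.

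Between day 24 and day 32 the question was what still changed after weaning. The light chain segment Iglv1 rose 12.4-fold (log2 3.63 ± 0.19, SE, n = 3 against 3; adjusted p = 1.10e-09), Jchain 11.6-fold (3.54 ± 0.22), Igkv8-30 9.71-fold (3.28 ± 0.25) and Igkv9-120 7.89-fold (2.98 ± 0.27). The amino acid transporter Slc6a14 rose 10.5-fold (3.39 ± 0.58), with log2 values of 2.35 without day 24 replicate 1 and 3.99 without day 24 replicate 2. Lct was 73.2-fold lower on day 32 (log2 difference -6.19 ± 0.35, adjusted p = 3.14e-09), the brush border phospholipase Plb1 31.4-fold (-4.97 ± 0.38), Fam151a 18.2-fold (-4.19 ± 0.17), Fabp1 13.1-fold (-3.71 ± 0.33) and the glucose transporter Slc2a2 12.7-fold (-3.66 ± 0.43). The day 32 levels of Lct (3.41) and Fam151a (3.89) lay below or among the array medians of 3.88 to 3.97. Their folds and rank depend on the background correction. Without day 32 replicate 3 the Plb1 difference was -4.37, and without day 32 replicate 2 that of Slc2a2 was -2.95. In all 527 genes were higher and 537 lower, 62 and 93 of them at least 2-fold.

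Of 10 enteroendocrine genes 5 fell and 0 rose (camera adjusted p = 2.86e-05, adjusted p = 0.0424 with an estimated correlation), led by Gip (11.6-fold; log2 difference -3.54, or -4.13 without day 32 replicate 1) and the granin Chga (3.12-fold). Of 14 cholesterol synthesis genes 10 rose, and 11 adjusted over the list alone (camera adjusted p = 3.87e-07, adjusted p = 0.179 with an estimated correlation), such as Lss (1.76-fold). Other calls of this list ended without single arrays. These were Sqle without day 24 replicate 1 (log2 0.77, limma adjusted p = 0.0523) and Msmo1 without day 24 replicate 2 (0.85, 0.0612) or replicate 3 (0.69, 0.146). Of 14 genes of lipoprotein assembly and fat absorption 5 fell and 1 rose, and 6 fell adjusted over the list alone (camera adjusted p = 0.000113, adjusted p = 0.108 with an estimated correlation), with Fabp1 and Apoc3 (4.08-fold) lower. Among B cell and plasma cell genes 3 of 5 rose (camera adjusted p = 0.000225, adjusted p = 0.179 with an estimated correlation), including Igha (7.10-fold). Of 4 genes of T cells and intraepithelial lymphocytes 3 rose (camera adjusted p = 0.000136, adjusted p = 0.0871 with an estimated correlation), Gzmb 6.05-fold and Gzma 5.59-fold. All 5 MHC class II genes rose (camera adjusted p = 0.000179, adjusted p = 0.280 with an estimated correlation), such as Cd74 (2.28-fold) and H2-Ab1 (2.15-fold). Of 10 glucocorticoid-induced genes 6 fell, and 7 adjusted over the list alone (camera adjusted p = 0.000193, adjusted p = 0.0561 with an estimated correlation). Among them were Mt2 (log2 difference -1.85), Mt1 (2.68-fold) and Tsc22d3 (2.23-fold). With only the arrays of these ages the calls of Mt2 (limma adjusted p = 0.134) and Mt1 (0.0755) ended. The Mt2 call also ended without day 24 replicate 1 (-1.26) or day 32 replicate 2 (-1.07). Of 11 interferon-stimulated genes 6 fell and 1 rose (camera adjusted p = 0.0105, adjusted p = 0.447 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.118), such as Rsad2 (2.38-fold). Prdm1 rose 2.28-fold, Slc10a2 2.64-fold, and Igf2 was 3.14-fold lower.

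The 18S ribosomal RNA control probe sets read 10.47 ± 0.33 on day 24 and 7.60 ± 0.51 on day 32, against means of 5.72 to 6.52 at the suckling ages. The gap between the 3' and 5' Gapdh control probe sets, which widens as RNA breaks down, was 0.53 ± 0.35 on day 24 and 0.02 ± 0.15 on day 32 (log2, SD, n = 3 each), with ranges of 0.27 to 0.92 and -0.11 to 0.18. The same gap of the Actb control probe sets was 0.61, 0.65 and 1.40 on day 24 and 0.59, 0.49 and 0.48 on day 32. By Actb only day 24 replicate 3 (1.40) stood apart. Quantile normalization moved the split of called genes to 455 higher and 758 lower, and the mean of a gene's probe sets moved it the other way, to 588 and 500. Without day 32 replicate 2 there were 288 higher and 283 lower, without day 24 replicate 3 there were 302 and 341, without day 32 replicate 1 the number lower was 324, and with only the arrays of days 24 and 32 there were 227 and 216. At these ages only day 24 replicate 2 had a high Xist level (8.68). With the Xist level as a covariate, 828 of the 1064 calls were kept in their direction, and 388 genes were higher and 453 lower.

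**Figure D4:**
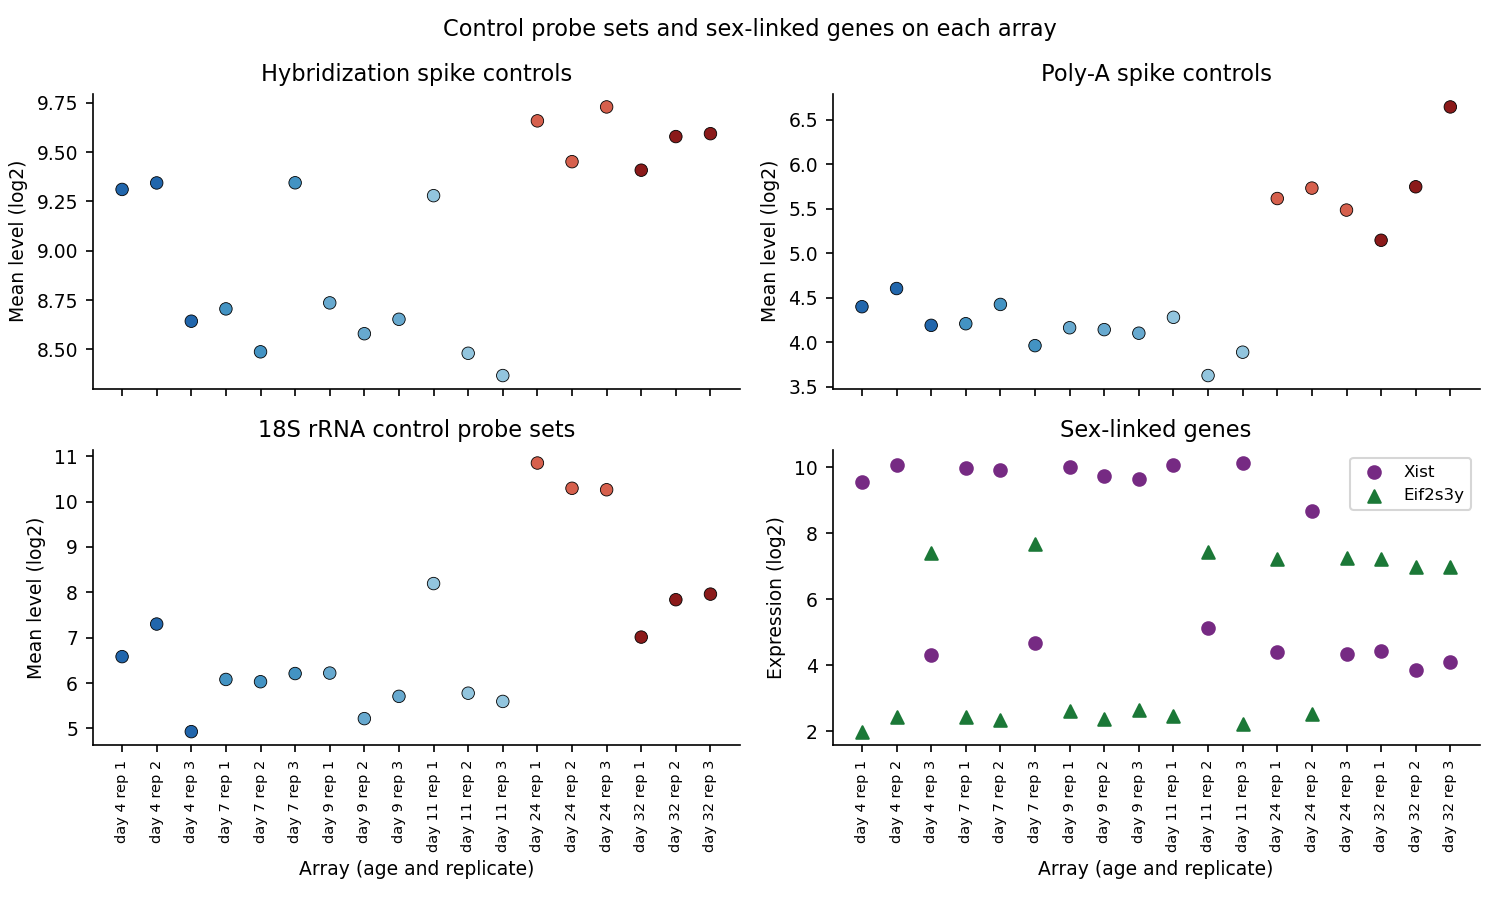
Mean log2 level of the hybridization spike controls, the poly-A spike controls and the 18S rRNA control probe sets, and log2 expression of Xist and Eif2s3y, on each of the 18 arrays in order of age and replicate. Poly-A controls average 4.17 before and 5.73 after weaning, 18S probe sets are highest on day 24 at 10.47, and Xist and Eif2s3y run opposite on every array.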

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

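The hybridization block, the higher hybridization group alone, the Xist covariate and the omission of 3 arrays were chosen after seeing the data. Outside the omission of single arrays, 128 counts of called genes stayed within 1.5 times and 39 moved, and of named genes 2933 results were the same and 146 lost their call; none reversed. Without a filter, more genes were tested, and 5248 were higher and 4999 lower after weaning, 3633 higher and 3528 lower on day 24 than on day 11, so that the higher side became the larger, and 2 changed from day 9 to day 11. With the log2 8 filter fewer genes were tested: 2729 changed across ages, 1279 were higher and 1586 lower after weaning (382 and 484 at least 2-fold), 59 and 62 for day 11 minus day 4, 1111 and 1288 for day 24 minus day 11, 278 and 299 for day 32 minus day 24, and 2 for day 7 minus day 4. The count for day 7 minus day 4 was 1 with probe-set means, 4 with quantile normalization, 3 with median centring, and the cause was not tested. Array weights gave 381 higher and 563 lower for day 11 minus day 4 and 114, 207 and 354 for the steps to days 7, 9 and 11; the cause was not tested. With only the arrays of the ages compared, fewer arrays set the spread: 28 and 24 for day 11 minus day 4, 227 and 216 for day 32 minus day 24, and 0 for the steps to days 7 and 11 (limma; 512 and 608 at an unadjusted p under 0.05 with all arrays). The hybridization block gave 187 and 297 for day 11 minus day 4, 3 for day 7 minus day 4 and 2 for day 11 minus day 9, and the Xist covariate 4 and 2 for those steps; the cause was not tested. Without the 3 arrays with the widest Gapdh gap (day 4 replicate 2, day 11 replicate 1, day 24 replicate 3) there were 33 and 25 for day 11 minus day 4 and 0 for the steps to days 7 and 11, with fewer arrays. Leaving out each array in turn gave 5488 to 6065 genes across ages, 2526 to 2736 higher and 3477 to 3652 lower after weaning (639 to 668 and 981 to 1017 at least 2-fold), 50 to 151 higher and 34 to 179 lower for day 11 minus day 4, 1973 to 2363 and 2568 to 2836 for day 24 minus day 11, 288 to 607 and 283 to 595 for day 32 minus day 24, and 0 to 9, 4 to 5 and 0 to 5 for the steps to days 7, 9 and 11. In these omissions 237 named gene results lost their call and 4497 did not. Of the lists, 45 results lost their call under an alternative, 418 were the same, and 1 gained it, the interferon list for day 24 minus day 11 under quantile normalization (adjusted p = 0.0313). An estimated correlation left 0 of 18 list calls after weaning, 0 of 9 for day 11 minus day 4, 4 of 13 for day 24 minus day 11 and 1 of 8 for day 32 minus day 24. No paired analysis was possible because the replicate numbers only name the arrays of different mice. Signal near the array medians of 3.88 to 3.97 limits folds of dim genes.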

Other observations

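Gene families were chosen by symbol after the data had been seen. After weaning 12 of 14 vacuolar ATPase genes, which acidify endosomes, fell and 2 rose (median log2 difference -1.10, camera adjusted p = 0.00712, adjusted p = 0.352 with an estimated correlation), with Atp6v1h and Atp6v1b2 at -1.52 and Atp6v0a2 at 0.95. Of 10 cathepsin protease genes 8 fell and 2 rose (camera adjusted p = 0.0150, adjusted p = 0.352 with an estimated correlation); Ctsa was 7.85-fold and Ctsh 4.33-fold lower, while Ctsc rose 2.52-fold. Of 63 sorting nexin and endosomal sorting genes 38 fell and 11 rose (camera adjusted p = 0.0870), with Snx8 at a log2 difference of -4.24.

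Of 9 claudins, proteins of tight junctions, 4 rose and 4 fell (camera adjusted p = 0.561), with Cldn15 4.14-fold and Cldn3 3.86-fold higher and Cldn8 9.41-fold lower. Of 6 keratins 3 rose, 1 fell and 2 did not pass (camera adjusted p = 0.0919), with Krt20 20.6-fold higher. Among 26 glycosyltransferases 15 rose and 8 fell (camera adjusted p = 0.0553); B3gnt7 rose 10.8-fold from a level of 3.96, within the range of the array medians, and the sialyltransferase St3gal1 was 27.1-fold lower. Of 14 cytochrome P450 genes of families 2 to 4, 12 rose and 1 fell (camera adjusted p = 2.91e-05, adjusted p = 0.288 with an estimated correlation), with Cyp4v3 40.0-fold higher. All 5 Hox genes fell from day 11 to day 24 (median -1.46, camera adjusted p = 0.0169, adjusted p = 0.122 with an estimated correlation), with Hoxb3 4.01-fold lower, and after weaning 4 were lower and 1 higher (camera adjusted p = 0.107). Between days 24 and 32, 2 of the 5 Hox genes rose (camera adjusted p = 0.00992, adjusted p = 0.102 with an estimated correlation), Hoxb6 3.65-fold and Hoxb3 2.94-fold. Over the same interval all 4 immunoglobulin segment genes rose (camera adjusted p = 0.00191 with an estimated correlation). From day 4 to day 11, 4 of 22 histone deacetylase and methyltransferase genes rose (0.0464 likewise). Mitochondrial ribosomal genes had a median of -0.26 from day 4 to day 11, with 2 of 76 lower (camera adjusted p = 2.08e-11, adjusted p = 0.864 with an estimated correlation).

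The genes that differed between days 24 and 32 may partly reflect where along the intestine the pieces were taken: an added list of 14 proximal markers, 9 of them also in the lists fixed earlier, had a median log2 difference of -0.32 (camera adjusted p = 0.000666, adjusted p = 0.0251 with an estimated correlation), and an added distal list of 10 genes, 9 of them likewise shared, one of 0.16 (camera adjusted p = 0.346). The same proximal list had a median of -0.30 for day 11 minus day 4 (adjusted p = 0.0220 with an estimated correlation), so its fall is not particular to days 24 and 32. From day 11 to day 24 it moved the other way, with a median of 0.27, 6 of 14 genes higher and 3 lower (camera adjusted p = 0.0407, adjusted p = 0.1535 with an estimated correlation). The distal list rose as well (median 0.58, camera adjusted p = 0.0407), while all 5 Hox genes were lower on day 24. Position was thus not separated from age in day 24 minus day 11 or between the stages either. From day 24 to day 32 Slc10a2 rose 2.64-fold, in an ileal bile acid list with 3 of 8 genes higher and 1 lower (median 0.30, camera adjusted p = 0.158), as did 2 of 5 Hox genes. For carried-over ribosomal RNA, the within-age slope on the 18S controls accounted for a median of 8.89% of the differences of 1064 genes (quartiles -12.5% and 30.2%). This cannot decide the question, because the 18S spread lay mainly on days 4 and 11 (SD 1.22 and 1.45), not on days 24 and 32 (0.33 and 0.51). The highest 18S arrays there, day 4 replicate 2 and day 11 replicate 1, also had the widest Gapdh gaps of their ages. The slope on the Gapdh gap, a test added after the gap was known to be wider on day 24 (0.53 against 0.02), accounted for a median of 10.2% (quartiles -6.87% and 29.1%). This cannot decide on RNA degradation either. The gap difference of -0.51 lay beyond the SDs of days 4, 11, 24 and 32 (0.38, 0.38, 0.35 and 0.15). Age stays open too, not tested apart from position.

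The genes that rose from day 4 to day 11 included the fat markers Car3 and Adipoq, and fat attached to the pieces could be a source. An added adipocyte list without those genes, 4 of them measured, had a median of -0.0129, which turned to 0.00 under quantile and cyclic loess normalization, so fat and age cannot be told apart with so few genes. RNA degradation was not decided either: 100% of the 116 genes kept their direction without the 3 arrays with the widest Gapdh gap, but every 1 of the 116 was separated between the ages, so that the omission could not have turned a direction. The Gapdh gap was 0.48 ± 0.38 on day 4 and 0.41 ± 0.38 on day 11 (SD, n = 3 each). Age remains an open explanation and was not tested apart from these.

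For the 1652 genes at least 2-fold higher or lower after weaning, technical sources and the sex of the mice were weighed. With the hybridization group as a block 99.8% (1648) were still called in their direction. With the Xist level as a covariate, which stands for the different shares of male and female patterns, 99.8% (1649) were. The hybridization controls reached 9.34 before weaning and began at 9.41 after it, so the block cannot part their level from stage. Of all 6292 genes called, 86.27% stayed called in their direction with the block and 86.47% with the Xist covariate. Within the higher group alone, with fewer arrays, 79.05% did. The within-age slope on the poly-A controls accounted for a median of -2.34% of the differences (quartiles -16.7% and 9.90%), and that on the 18S controls, a test added after their levels were known, for -1.30% (quartiles -12.8% and 7.84%). For the 1652 genes the Xist value argues against sex as the whole cause, and the block value against the group as drawn. Neither slope can decide its cause, because both are carried beyond the spread within ages. Poly-A levels before weaning lay near the array medians, and their widest SD within an age (0.75, day 32) was below the stage gap of 1.56. For 18S the widest SD was 1.45, on day 11, and the stage gap 2.88. The labels name no batch, but the hybridization and poly-A levels did not overlap between the stages and the mean 18S level was higher after weaning. A difference in hybridization, labelling or carried-over ribosomal RNA therefore stays open as a source, and a biological difference between the stages remains a hypothesis.

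Random assignments of the 18 arrays to ages were drawn, 100 with the real one. For the F test 1 of the 100, the real one, gave as many as 5897 genes; the highest other gave 2141, which points to a structure of the samples. For after minus before weaning 1 of 100, the real one, gave as many as 6292, and the highest other gave 0. Random assignments mix the stages within ages, so the stage difference then widens the residual spread and lowers the counts. The draws thus show only that the real assignment ranked first of 100, and they do not test a source that coincides with stage. The 10 splits of 6 arrays cannot give a share under 0.05. The real counts and highest others were 249 and 3 for day 11 minus day 4, 5109 and 0 for day 24 minus day 11, 1064 and 4 for day 32 minus day 24, 7 and 0 for day 7 minus day 4, 4 and 0 for day 9 minus day 7, and 4 and 1 for day 11 minus day 9.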
